A study of Mus musculus with 8 samples.

How the data were processed

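Poly-A RNA was sequenced from pro-B cells sorted from the bone marrow of 8-week-old mice, with 75-base single-end reads on a NextSeq instrument, per the labels' protocols. The sort kept cells positive for B220 and Cd43 and negative for IgM and CD25. The 8 samples were 4 controls and 4 Setd2 knockouts, grouped by the genetic alteration the labels give, and all carried the same sequencing batch. The labels do not name the animal behind a replicate number, so every p-value measures the spread between these samples, which may be partly technical.

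Reads were aligned with STAR 2.5.1 and the build was mm10, per the submitters' processing notes. Immunoglobulin sequences were assembled with the TRUST repertoire algorithm, per the series design text, and its version is not given in the sources used here. Each sample had a table of assembled contigs and a table of read counts per gene segment for the heavy and for the light chain, as deposited by the authors. The read count per contig and per segment is a whole number with no normalization, per the file headers and values. The expression score of each clonotype, per the file headers an estimate, came out as a whole number of reads for 100% of contigs when multiplied by the CDR3 length in bases, within 0.01. Lengths under 48 bases for heavy and 39 bases for light chains were set to these values in that product. The result is called CDR3-spanning reads here. The contig read count was larger than this number by up to 30.1 times for the light chain of control 3 and up to 2.95 times for the heavy chain of knockout 2. Reads counted in several contigs may be the source, which was not tested.

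The library size in the files equalled the sum of the segment counts, so it is the number of reads on the chain's locus. The depth of the whole library is not known. Heavy-chain locus reads ran from 12102 to 100600 per sample and light-chain locus reads from 5956 to 144978. Setd2 transcript levels were not analysed here, so the knockout was not checked on RNA. Contigs with a stop or frame shift numbered 0 in every sample, so the productive share could not be compared.

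A clonotype is a distinct complete CDR3 nucleotide sequence. Its V gene was used where the contig listed a single V gene, and its V family where the listed genes shared a family. The contig tables gave no D gene, so D families were assigned by a match of at least 8 bases to the D segments of GENCODE M21, an addition made after seeing the files. V segments form a family of near-identical copies, and reads of close paralogs can be divided between them by the alignment, so values of single V genes are uncertain to that extent. Per-sample readouts were compared by a two-sided exact permutation test of the difference of group means over 70 arrangements, with a smallest possible p of 0.0286. A readout was called at an unadjusted p under 0.05, and Benjamini-Hochberg values were computed over the readouts of each chain and over 34 added readouts. Numbers of clonotypes at equal reads are means over 100 draws. Counts and ratios were tested as log2 values, so a fold between groups is a ratio of geometric means and can differ from the ratio of the arithmetic means printed beside it.

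Counts per V gene were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the total of V counts as library size, no further scaling, at least 10 counts per gene and Benjamini-Hochberg adjusted p under 0.05. Each test was run on simulated data with known changes. When no other gene gave up share, edgeR recovered 73.3% of 16-fold and 16.5% of 4-fold changes for heavy-chain segment counts, 80.9% and 12.3% for light-chain segment counts, 65.0% and 32.5% for heavy V usage, and 100% and 65.0% for light V usage. When the changed genes took share from the others, 15.7% of unchanged genes were called for heavy V usage, 23.1% for light V usage, 1.36% for heavy and 3.31% for light segment counts, and 25.0% of 4-fold changes were recovered for light V usage. DESeq2 1.42.0 was an alternative. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

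The samples, tests, named genes, gene lists and a first set of alternatives were chosen before the data were examined. Named V genes were those past the threshold, completed where fewer than 12 passed by the genes of lowest p, and further the 6 most used VH genes of the controls, IGHV5-2, the JH genes and the D families. The lists were proximal VH (families 2 and 5), intermediate VH (families 3, 4, 6, 7 and 9 to 16), distal VH (families 1 and 8), JH genes, D families, upstream and downstream Jk genes and lambda genes. Lists of markers for other B-lineage cells were the switched constant regions IGHG, IGHA and IGHE, the IGHD constant region, and rearranged light chains. Alternatives were each replicate left out, the replicate number as a block, other clonotype definitions, other scalings and filters, and several that were added after seeing the data. The readouts of constant regions, effective gene numbers, D families and germline V ends were also added after seeing the data. Intervals for the share of a single sample are 95% Wilson intervals, a count of 0 was given an upper limit of 3 counts, and both cover counting error only.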

Results

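The heavy and light immunoglobulin chains of pro-B cells were read from poly-A RNA of 4 control and 4 Setd2 knockout samples. Pro-B cells are the bone marrow stage at which the heavy-chain locus is rearranged, and Setd2 encodes a methyltransferase of histone H3. Heavy-chain locus reads numbered 89908, 89432, 64488 and 76161 in controls 1 to 4 and 54626, 41368, 12102 and 100600 in knockouts 1 to 4. Light-chain locus reads ran from 84230 to 118807 in controls and from 5956 to 144978 in knockouts. Knockout 3 was the shallowest sample for both chains. Complete heavy-chain CDR3 sequences numbered 3141 over the controls and 741 over the knockouts. Values are means ± SD with n = 4 per group unless stated otherwise, and folds and ratios of groups are of geometric means.

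The size of the heavy-chain repertoire was compared first. The CDR3 is the junction of the V, D and J segments and marks a clone of B-lineage cells. Distinct heavy-chain CDR3 sequences numbered 785 ± 83.2 in controls and 185 ± 78.0 in knockouts, a ratio of geometric means of 4.66 of controls over knockouts (exact permutation p = 0.0286). At an equal number of 120 reads the numbers were 103 ± 8.58 and 65.1 ± 8.40, a fold of 0.633 (exact permutation p = 0.0286). The 10 largest clonotypes held 13.8% ± 8.97 of the contig reads of clonotypes in controls and 41.4% ± 9.45 in knockouts (exact permutation p = 0.0286). The highest control was at 26.3%. A sample with fewer reads or clonotypes tends to give a larger share, and knockout 3 had 73 clonotypes from 120 reads. The shares of single clonotypes that follow are of CDR3-spanning reads, so the 2 measures cannot be set side by side. The largest clonotype of knockout 4, with the protein sequence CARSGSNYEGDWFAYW and IGHJ3, held 203 of 1227 CDR3-spanning reads, or 16.5% (95% Wilson interval 14.6 to 18.7). With the 2 sequences 1 base away, of 62 and 29 reads and the former of the same protein sequence, it held 294 reads, or 23.96% (21.7 to 26.4), and whether these are separate clonotypes or read errors was not determined. In knockouts 1 to 3 the largest clonotype held 4.30% (3.12 to 5.90), 3.15% (2.16 to 4.57) and 7.50% (3.996 to 13.6), with 0 sequences 1 base away, and in the controls 0.667% to 1.29%, or up to 1.42% with such sequences. Clonality, which is 0 for even and 1 for fully uneven repertoires, was 0.0694 ± 0.0347 and 0.154 ± 0.0902 (exact permutation p = 0.143), and the difference of 0.0845 was 0.0476 without knockout 4. Heavy-chain contig reads per 1000000 locus reads were 47176 ± 6574 and 36263 ± 29249 (exact permutation p = 0.257), and without knockout 2 the knockout mean was 21777 and the log2 difference -1.13 in place of -0.66. Without knockout 3 the knockout mean was 42952.5 and the log2 difference -0.36. With Benjamini-Hochberg adjustment over the heavy-chain readouts, the 3 differences with p = 0.0286 by exact permutation had an adjusted p of 0.100 and did not pass. Without knockout 3, more reads could be drawn per sample, and the fold at equal reads was 0.381 with the smallest exact permutation p of 0.0571.

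**Figure D1:**
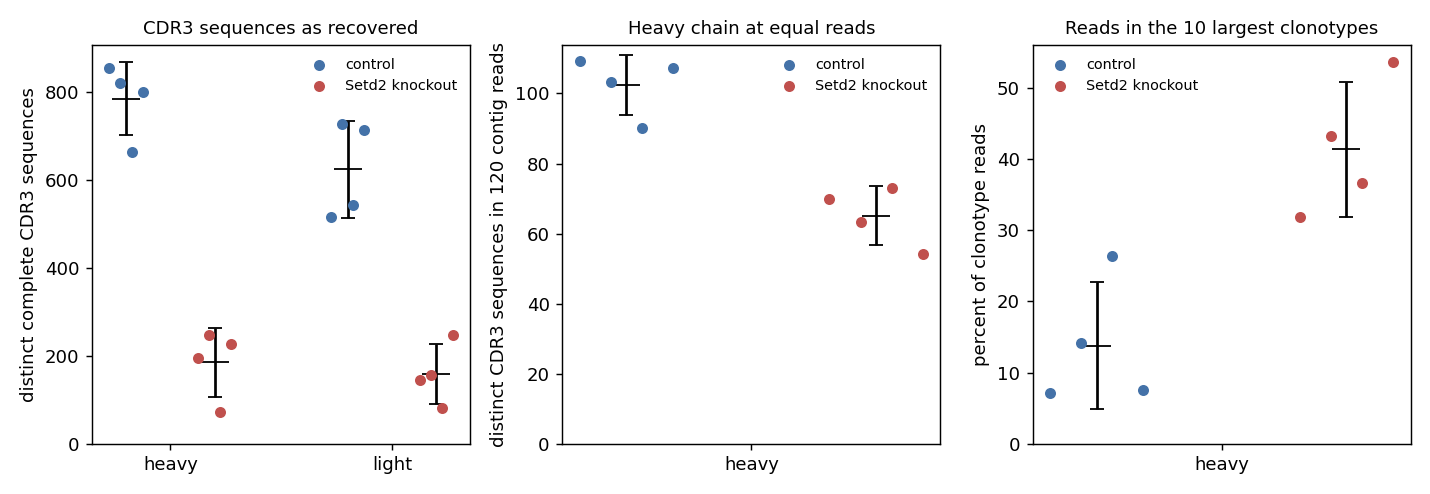
Distinct complete CDR3 sequences per sample for the heavy and light chain (left), distinct heavy-chain CDR3 sequences in 120 contig reads (centre) and percent of the contig reads of heavy-chain clonotypes in the 10 largest clonotypes (right). Points are samples, horizontal lines are group means and bars are SD with n = 4. All knockouts lie below all controls on the left and centre and above them on the right.

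Use of VH families along the locus was compared because joining of the distal families depends on contraction of the locus more than that of the families near the D segments. Proximal families 2 and 5 made up 11.8% ± 1.63 of clonotypes in controls and 17.7% ± 3.97 in knockouts (exact permutation p = 0.0571). Distal families 1 and 8 made up 73.5% ± 2.04 and 68.0% ± 5.98 (exact permutation p = 0.20), a difference of -5.44 percentage points that was -2.86 without knockout 1. The intermediate families made up 14.7% ± 2.81 and 14.3% ± 2.29 (exact permutation p = 0.83), with a difference that ran from -1.77 to 0.266 percentage points with 1 sample left out and turned without knockout 4, control 2 or control 3. The distal to proximal ratio was 6.33 ± 0.949 in controls and 4.07 ± 1.29 in knockouts, a fold of 0.624 (exact permutation p = 0.0857, adjusted p = 0.171). None of these 4 differences passed the test.

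Reads per VH gene segment gave the use of single genes. They weigh each clone by its RNA, so 1 large clone can raise the share of its gene. VH reads of the knockouts were concentrated on fewer genes: the effective number of VH genes, from the entropy of their reads, was 63.1 ± 3.10 in controls and 33.8 ± 16.4 in knockouts (exact permutation p = 0.0286, adjusted p = 0.139 over the added readouts). In knockout 4, IGHV5-9-1 of the proximal family 5 held 27.6% of VH reads (95% Wilson interval 27.3 to 28.01) and the distal gene IGHV1-81 held 23.9% (23.5 to 24.2). In knockout 1, IGHV2-2 of the proximal family 2 held 16.3% (15.8 to 16.7). IGHV5-9-1 and IGHV2-2 were chosen after their values were seen. The largest clonotype of knockout 4 had no V gene listed, and the 2 sequences 1 base from it listed IGHV1-81. Together these sequences held 23.96% of the CDR3-spanning reads of knockout 4. How much of the IGHV1-81 share came from them was not tested. No large clonotype was matched to the IGHV5-9-1 share, since the clonotypes of rank 2 to 5 in knockout 4 listed genes of family 1. Family 5 held 31.6% of VH reads and 11.05% of clonotypes in that sample. Without knockout 4 the fold of geometric means in effective VH genes was 0.627 in place of 0.479.

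Of 130 VH genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, and at an unadjusted p under 0.05 it gave 2 higher and 34 lower in knockouts, while DESeq2 called 6, 3 higher and 3 lower. In 32 genes all knockouts were below all controls by share of VH reads and in 0 genes above. For a single gene, chance gives such a separation at a rate of 2.86% over both directions. The shares sum to a fixed total, so a few genes with large shares lower all others at once. The genes are therefore not independent, and the count of 32 does not test chance. The 4 genes of lowest p were lower in the knockouts on average and did not pass, each with an adjusted p of 0.0514 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They were the distal genes IGHV1-47 (chromosome 12, 114991108 to 114991401, mm10) and IGHV1-66 (115593110 to 115593403) and the intermediate genes IGHV13-2 (114357761 to 114358060) and IGHV9-2 (114109001 to 114109430). IGHV1-47 held 0.312% ± 0.222 of VH reads in controls and 0.00871% ± 0.0151 in knockouts, a log2 fold change of -4.89 with SE 1.15 that was -6.97 without knockout 2 and -4.29 without control 4. IGHV13-2 had a log2 fold change of -4.36 (SE 1.08), or -5.79 without knockout 2, IGHV9-2 of -3.54 (SE 0.93) and IGHV1-66 of -3.01 (SE 0.76). IGHV3-4, IGHV6-7, IGHV1-25, IGHV2-6, IGHV1-17, IGHV3-8, IGHV1-36 and IGHV15-2 followed, with adjusted p from 0.0720 to 0.0831 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. IGHV15-2 alone among these 8 had a higher mean in knockouts, and its log2 fold change of 4.32 (SE 1.44) was 1.59 without knockout 3. Without knockout 2 the count of called genes was 4, without control 4 it was 5, and with every V gene seen tested it was 6. With the replicate number as a block it was 15, all lower, though whether that number pairs the samples is not known.

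Among the fixed lists, 0 of 18 proximal, 0 of 33 intermediate and 0 of 79 distal VH genes passed edgeR's test over all genes, with 1 higher and 2 lower, 1 higher and 9 lower, and 0 higher and 23 lower at an unadjusted p under 0.05. DESeq2 called 0 proximal, 4 intermediate and 2 distal genes. Adjusted over the list alone, edgeR called 0 proximal genes, 6 intermediate genes lower (IGHV13-2, IGHV9-2, IGHV3-4, IGHV6-7, IGHV3-8 and IGHV3-5) and IGHV15-2 higher, and 2 distal genes lower (IGHV1-47 and IGHV1-66). The tallies and medians over all VH genes depended on the scaling, while IGHV1-47, IGHV13-2, IGHV9-2, IGHV1-66 and IGHV15-2 kept their directions with TMM and DESeq2. The median log2 fold change of all VH genes was -0.82 by share of VH reads, 0.18 with TMM scaling and 0.20 with DESeq2, and the counts at an unadjusted p under 0.05 became 14 higher and 11 lower with TMM and 17 and 13 with DESeq2. The medians of the proximal and distal genes were -0.09 and -1.11 by share, 1.12 and 0.04 with TMM, and 1.14 and 0.12 with DESeq2, an order that a scaling of whole samples could hardly change. Few genes could be tested by clonotypes, with medians of -0.87 for 2 proximal and 0.36 for 8 distal genes, an order opposite to that of the family shares over all clonotypes.

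The 6 VH genes most used by the controls were IGHV1-81, IGHV1-26, IGHV3-6, IGHV9-3, IGHV1-55 and IGHV14-2. IGHV9-3 held 3.39% ± 1.63 of VH reads in controls and 0.864% ± 0.349 in knockouts, and IGHV1-55 held 3.31% ± 0.833 and 0.974% ± 0.615, with no overlap between the groups. Their adjusted p were 0.113 and 0.141 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. IGHV1-81 held 5.20% ± 1.90 and 10.8% ± 9.35 (6.40% in knockouts without knockout 4), IGHV1-26 4.06% ± 0.820 and 3.06% ± 1.77, IGHV3-6 3.73% ± 0.292 and 4.01% ± 3.38 (2.38% without knockout 2, where the direction turned), and IGHV14-2 3.30% ± 0.782 and 1.92% ± 1.25. IGHV5-2 (chromosome 12, 113578504 to 113578990, mm10), the proximal gene also known as VH81X, held 0.0489% ± 0.0434 and 0.0505% ± 0.0789, a log2 fold change of 0.29 with SE 0.97 that was -1.64 without knockout 4, where the knockout mean was 0.0114%, and 1.10 without control 4. By clonotypes, 397 in all, edgeR called 0 of 12 VH genes, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. These were clonotypes with a single listed V gene, 6 to 30 in each knockout. IGHV1-9 had the lowest p among the 12 genes, at 9.05% ± 3.18 and 1.88% ± 2.19 of such clonotypes (adjusted p = 0.827 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The others were IGHV1S22, IGHV5-4, IGHV1-75, IGHV1-81, IGHV1-7, IGHV1-18, IGHV14-3, IGHV5-17, IGHV8-8, IGHV1-58 and IGHV7-3, with adjusted p from 0.827 to 0.973 by the same edgeR test with Benjamini-Hochberg adjustment.

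The JH and D segments of the clonotypes were compared next. IGHJ1, the JH segment nearest the D segments, was used by 10.5% ± 1.35 of clonotypes in controls and 14.2% ± 2.39 in knockouts (exact permutation p = 0.0286, adjusted p = 0.100). By share of reads the IGHJ1 difference of 6.22 percentage points did not pass (exact permutation p = 0.171). IGHJ2 made up 44.7% ± 1.08 and 39.5% ± 7.07 (exact permutation p = 0.20) and IGHJ3 18.7% ± 2.499 and 20.9% ± 2.91 (exact permutation p = 0.286). IGHJ4 made up 26.1% ± 4.45 and 25.4% ± 8.70 (exact permutation p = 0.943), with a difference that ran from -2.80 to 3.45 percentage points with 1 sample left out and turned without knockout 4, control 2 or control 4. D family 1 (DFL16) was assigned to 36.2% ± 4.25 and 40.3% ± 6.73 and D family 2 (DSP2) to 48.3% ± 2.99 and 47.9% ± 7.35, with exact permutation p of 0.343 and 0.943. The D family 2 difference ran from -3.90 to 1.63 percentage points with 1 sample left out and turned without knockout 1 or 2 or control 2 or 4. D family 3 (DST4) made up 4.26% ± 1.88 and 2.74% ± 1.16 and D family 4 (DQ52) 10.7% ± 1.69 and 8.69% ± 4.14, with exact permutation p of 0.257 and 0.486. Mean heavy CDR3 length was 13.4 ± 0.118 amino acids in controls and 13.7 ± 0.222 in knockouts (exact permutation p = 0.0857).

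**Figure D2:**
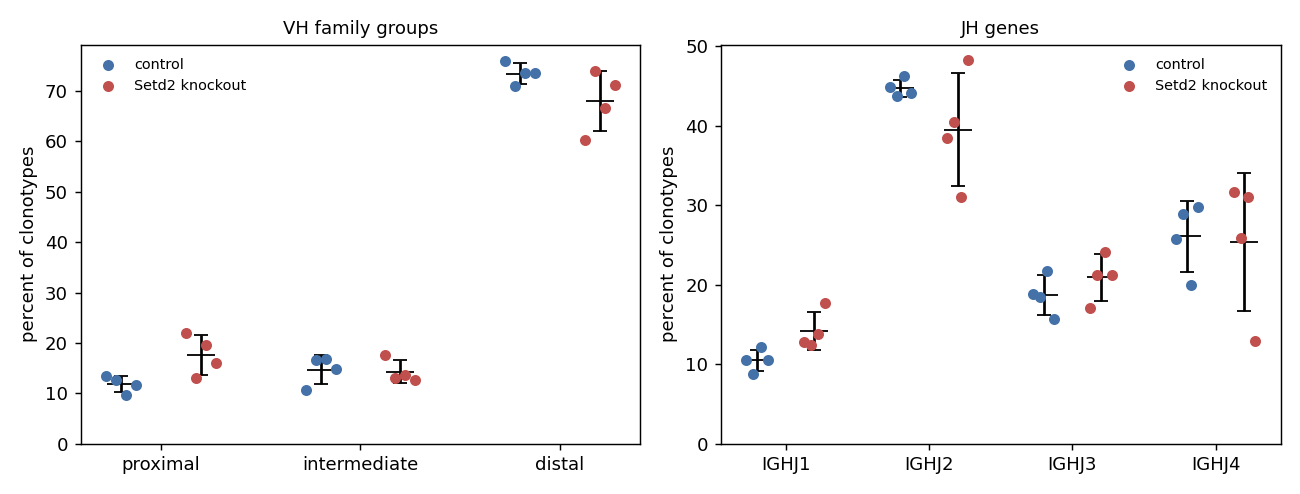
Percent of heavy-chain clonotypes using proximal, intermediate and distal VH families (left) and each JH gene (right). Points are samples, horizontal lines are group means and bars are SD with n = 4. The groups overlap in each panel except for IGHJ1, at 10.5% and 14.2% on average.

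Constant-region reads were used as markers of B-lineage cells later than the pro-B stage. IGHM, the constant region of unswitched cells, made up 45.6% ± 2.92 of heavy constant-region reads in controls and 68.4% ± 17.0 in knockouts (exact permutation p = 0.0286, adjusted p = 0.139). IGHG, which marks switched B cells and plasma cells, made up 26.1% ± 6.41 and 9.29% ± 5.04 (exact permutation p = 0.0286, adjusted p = 0.139). IGHA, the other abundant switched class, made up 27.3% ± 7.36 and 21.6% ± 12.7 (exact permutation p = 0.514), and without knockout 3 the knockout mean was 27.5% and the difference 0.159 in place of -5.71 percentage points. The IGHA difference was -9.86 percentage points without knockout 4 and -9.12 without control 1. IGHD, expressed by mature naive B cells, made up 0.860% ± 0.153 and 0.644% ± 0.133 (exact permutation p = 0.0857), and IGHE had 1 to 25 reads per sample. IGHM reads themselves were 16425 ± 4602 and 15761 ± 6847 (exact permutation p = 0.771), with a log2 difference of -0.36 to 0.08 with 1 sample left out that turned without knockout 2, knockout 3 or control 1. Knockout 3 had the highest IGHM share, 92.7% (95% Wilson interval 92.2 to 93.2), and without it the difference in IGHM share was 14.7 in place of 22.8 percentage points. Among contigs with an assigned constant region, 99.9% ± 0.134 and 95.7% ± 8.26 of reads were switched (exact permutation p = 0.371), or 99.9% in both groups without knockout 3. IGHA was assigned to 1075 of these 1133 contigs and IGHM to 5, with 43 IGHG among 185 contigs of control 1 and 4 contigs in all in knockout 3. IGHM was the largest class by segment reads, so this contig share does not measure the extent of switching.

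**Figure D3:**
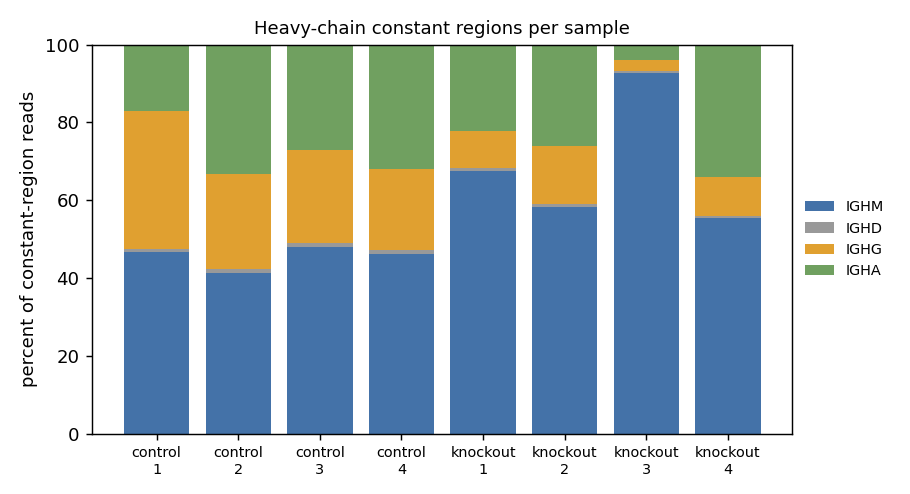
Percent of heavy constant-region reads on IGHM, IGHD, IGHG and IGHA in each sample. IGHE, with at most 25 reads in a sample, is not drawn. IGHM made up 41.4% to 48.02% in controls and 55.4% to 92.7% in knockouts.

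Light chains, which are rearranged mostly after the pro-B stage, were present in all samples. Distinct light-chain CDR3 sequences numbered 625 ± 111 in controls and 158 ± 68.5 in knockouts, a fold of 0.237 (exact permutation p = 0.0286, adjusted p = 0.171). Per 1000000 locus reads the fold was 0.600 and did not pass (exact permutation p = 0.343), and without knockout 3 it was 0.383 with the smallest exact permutation p of 0.0571. At an equal number of 189 contig reads the numbers were 138 ± 37.4 and 92.6 ± 14.6 (exact permutation p = 0.0857). Control 3 gave 82.4 there against 152 to 160 in the other controls. At an equal number of CDR3-spanning reads, an alternative added after seeing the data, the means were 142 and 93.5 (exact permutation p = 0.0286). The ratio of light to heavy contig reads was 4.41 ± 7.48 and 0.617 ± 0.378 (exact permutation p = 0.343), and without control 3 the control mean was 0.663 and the log2 difference -0.32 in place of -1.47. Downstream Jk genes made up 35.5% ± 3.78 and 34.7% ± 8.19 of kappa clonotypes (exact permutation p = 0.857), with a difference that ran from -2.71 to 3.17 percentage points with 1 sample left out and turned without knockout 2 or control 1. Lambda clonotypes were 1 of 727 in control 2 and 0 of 631 over the knockouts. By counting error alone this allows up to 0.475% of the assembled clonotypes. Lambda held larger shares of the segment reads, so the clonotype share does not measure the extent of lambda use. By segment reads, lambda V genes made up 4.43% ± 1.32 and 6.34% ± 2.33 of light V reads (exact permutation p = 0.229). Lambda constant regions, compared after seeing the data, made up 3.15% ± 0.728 and 9.51% ± 9.39 of light constant reads (exact permutation p = 0.0286, not in an adjusted family), and the difference of 6.36 percentage points was 1.67 without knockout 3. Mean light CDR3 length was 10.98 amino acids in both groups (exact permutation p = 1).

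Of 113 light V genes tested by reads, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with 3 higher and 18 lower at an unadjusted p under 0.05, and DESeq2 called 9, 6 higher and 3 lower. In 22 genes all knockouts were below all controls by share of light V reads and in 1 gene above. For a single gene, chance gives such a separation at a rate of 2.86% over both directions. The shares depend on each other here too, so these counts do not test chance. IGKV1-99 (chromosome 6, 68541658 to 68542422, mm10) held 0.221% ± 0.163 of light V reads in controls and 0.00486% ± 0.00616 in knockouts (log2 fold change -5.12, SE 1.22, or -5.75 without knockout 2). IGKV8-34 had a log2 fold change of -5.10 (SE 1.27), or -6.38 without knockout 1, and both had an adjusted p of 0.0844 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. IGKV2-112, IGKV3-8, IGKV8-26, IGKV3-4, IGKV8-28, IGKV11-125, IGKV1-132, IGKV2-109, IGKV8-19 and IGKV1-88 followed, with lower means in knockouts and adjusted p from 0.0929 to 0.143 by the same edgeR test with Benjamini-Hochberg adjustment. The median log2 fold change of light V genes was -0.64 by share of reads, 0.15 with TMM and 0.21 with DESeq2, and 15 genes were then higher and 11 lower with TMM at an unadjusted p under 0.05. By clonotypes, edgeR called 0 of 26 light V genes, with 1 higher at an unadjusted p under 0.05 and 0 calls by DESeq2. That gene was IGKV12-46, at 2.16% ± 0.343 in controls and 5.87% ± 0.718 in knockouts (adjusted p = 0.248 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). These are shares of clonotypes with a single listed V gene, 30 to 73 in each knockout. By reads IGKV12-46 was at 1.85% ± 0.508 and 2.13% ± 0.636 (1.83% without knockout 1, where the direction turned). IGKV6-15, IGKV1-110, IGKV6-23, IGKV6-25, IGKV1-135, IGKV14-111, IGKV3-7, IGKV5-48, IGKV19-93, IGKV4-86 and IGKV12-98 followed by clonotypes, with adjusted p from 0.456 to 0.890 by the same edgeR test with Benjamini-Hochberg adjustment.

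Identical heavy-chain CDR3 nucleotide sequences in different samples were counted last. Pairs of controls shared 2 to 6 sequences, pairs of knockouts shared 0, and pairs of a control and a knockout shared 0 to 8. Smaller samples share fewer sequences by chance. The knockouts held 73 to 248 sequences and the controls 665 to 855, so the 0 does not show less sharing among knockouts. The mean share of identical sequences among all sequences of a pair within groups minus between groups was -0.00104 percentage points (exact permutation p = 0.914), a sign that turned without any 1 of the knockouts or control 3. The pair with 8 was knockout 3 and control 3, and without knockout 3 the difference was 0.0995 with the smallest exact permutation p of 0.0571.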

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

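Readouts in this part that concern constant regions, D families or segment reads were chosen only after the data were seen. A sample is named here where its gap to the nearest sample of its group took up nearly the whole range of the group. Chance gives about 1 in 20 such groups, and 11 of 108 groups of samples had one.

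Control 3 stood apart for the light chain. Its light-chain contig reads per 1000000 locus reads were 647655 against 19435 to 25093 in the other controls. Its ratio of light to heavy contig reads was 15.6 against 0.559 to 0.786. Its light-chain clonotypes at equal reads were 82.4 against 152 to 160. The contig reads of this sample exceeded its CDR3-spanning reads 30.1 times.

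Knockout 3, the shallowest sample, had a switched share of 83.3% of contig reads against 99.8% to 100% in the other knockouts, from 5 of 6 reads (95% Wilson interval 43.6 to 97.0). Its lambda constant regions IGLC2 and IGLC3 made up 22.7% of light constant reads (21.4 to 24.1) against 3.18% to 3.74%.

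Other single values stood apart as well. Control 2 had the only lambda clonotype of the controls, a share of 0.138% (95% Wilson interval 0.0243 to 0.775). IGHM reads of control 1 were 23293 against 13612 to 14736 in the other controls. IGHG3 made up 1.71% of constant-region reads in knockout 1 (1.56 to 1.86) against 0.0196% to 0.162%. The lambda constant region IGLC1 made up 2.13% of light constant reads in knockout 4 (2.02 to 2.24) against 0.843% to 0.978%. D family 3 made up 7.06% of clonotypes with an assigned D in control 2 against 3.10% to 3.47%, and 4.48% in knockout 1 against 2.08% to 2.22%.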

How the results depend on the processing

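Alternatives using CDR3-spanning reads, merged sequences, locus reads, segment reads or the removal of knockouts 3 and 4 together were chosen only after seeing the data. Where an exact test of a main readout could pass, 87 of 100 recomputed values kept their side of the threshold and 97 their direction, and the cause of the exceptions was not tested unless given. In 210 further values, with a replicate left out or as a block, no readout could pass, so these say nothing about the calls: all 51 for readouts that had passed kept their direction only. Heavy-chain reads passed when unscaled (log2 difference -1.62) and by CDR3-spanning reads (-0.99), and light-chain reads when unscaled (-3.08). Control 3 held 54552 of the 62135 light-chain contig reads of the controls. Without it the scaled difference in light-chain reads was -0.53 in place of -1.75. Clonality passed with sequences within 1 base merged (0.0714), reads thinned (0.0672), CDR3-spanning reads (0.0647) and both of the last (0.0505). Light-chain clonotypes at equal reads passed with sequences merged (-0.63) and by CDR3-spanning reads (-0.61). Light-chain clonotypes per 1000000 locus reads (-0.74) and IGHJ1 by share of reads (6.22 percentage points) no longer passed. With knockout 3 also left out, the former was -1.38. By segment reads the switched share passed (-22.6 percentage points), and the lambda share reversed and passed (6.36, exact p = 0.0286, or 1.67 with knockout 3 also left out). Heavy-chain clonotypes at equal reads ranged from -1.39 to -0.57 with a replicate left out, and were -1.33 without knockouts 3 and 4, where more reads were drawn. With 3 samples in a group the smallest exact p is 0.0571.

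Heavy-chain V genes past the threshold numbered 0 to 5 with a replicate left out, 6 with DESeq2 and 6 with every V gene seen. The 4 without knockout 2 and 5 without control 4 were the only calls among the replicates left out. Light-chain V genes numbered 9 with DESeq2. Correlations of same-numbered samples were 0.0967, 0.0728, -0.0460 and 0.0742 for heavy and 0.178, -0.0401, 0.0175 and 0.0774 for light V genes. Those of differently numbered samples ran from -0.146 to 0.0884 for heavy and from -0.260 to 0.280 for light V genes. Low correlations of V genes cannot exclude that the replicate number pairs the samples, and the labels do not settle it. With the number as a block, 15 heavy V genes passed, all lower, and 0 light V genes. Single readouts kept their values and could not pass, since the smallest exact p of the block is 0.125. For the sharing of heavy-chain sequences between samples no block could be fitted, since it is a property of pairs of samples. For D families a replicate left out is the only alternative given here, since the contig tables gave no D gene. Alternatives for the productive share were not run, since 0 sequences were non-productive. Depth limits knockout 3 most, with 120 reads over complete heavy-chain CDR3 sequences.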

Other observations

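The tests of explanations in this part were chosen only after the results were seen. V ends of the heavy-chain clonotypes, the last 30 bases before the CDR3, were compared with 148 germline VH genes of GENCODE M21. The contigs also list V genes without a position there, such as IGHV1S22. A V end from a germline gene or allele absent from the 148 could therefore count as different. They were identical to a germline gene in 74.1% ± 0.785 of clonotypes in controls and 84.0% ± 8.80 in knockouts (SD, n = 4 each, exact permutation p = 0.0286). Knockout 3 had the highest share, 27 of 28 or 96.4% (95% Wilson interval 82.3 to 99.4), and without it the difference was 5.76 in place of 9.90 percentage points, with the smallest exact permutation p of 0.0571. The subclasses IGHG2B and IGHG2C made up 22.8% ± 5.02 of constant-region reads in controls and 8.09% ± 4.88 in knockouts, and IGHG1 made up 3.15% ± 1.59 and 0.711% ± 0.488 (exact permutation p = 0.0286 for each, adjusted p = 0.139). The remaining subclass IGHG3 made up 0.159% ± 0.0840 and 0.489% ± 0.814 (exact permutation p = 0.886). Its difference of 0.330 percentage points was -0.0757 without knockout 1.

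Other segments went different ways. VH family 9 held 4.73% ± 1.87 of VH reads in controls and 1.24% ± 0.432 in knockouts, and family 13 held 0.137% ± 0.0692 and 0.00535% ± 0.00852 (exact permutation p = 0.0286 for each, adjusted p = 0.214 over 15 families), the latter at 0.00118% without knockout 2. Reads on JH1 made up 55.7% ± 1.66 and 65.3% ± 7.96 of JH reads (exact permutation p = 0.0286, adjusted p = 0.139), and the difference was 5.68 in place of 9.55 percentage points without knockout 3. The effective number of kappa V genes was 51.5 ± 2.03 and 31.5 ± 11.6 (exact permutation p = 0.0286, adjusted p = 0.139). Reads on the lambda constant regions IGLC2 and IGLC3 were 1259 ± 187 and 1282 ± 570 (exact permutation p = 0.886), with a log2 difference of -0.33 to 0.12 with 1 sample left out that turned without knockout 2, knockout 3 or control 3. IGKC reads were 50248 ± 6963 and 30618 ± 24669 (exact permutation p = 0.143), with 2810 in knockout 3 and 62691 in knockout 4, and without knockout 3 the fold of geometric means was 0.741 in place of 0.389.

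A candidate explanation for many VH and kappa reads of these libraries is RNA of class-switched B-lineage cells in the sort, which excluded IgM and CD25 but no switched isotype, although its B220 and Cd43 gates would remove many switched B cells and plasma cells. Over the 8 samples, log2 VH reads followed log2 switched constant-region reads (r = 0.981, permutation p = 0.00208, adjusted p = 0.00347 over 5 relations; rho = 0.833, permutation p = 0.0154), with r = 0.718 without knockouts 2 and 3 and 0.981 within groups, and log2 IGKC reads did too (r = 0.987, permutation p = 0.00122; rho = 0.833, permutation p = 0.0154; 0.801 without the same samples), while V ends that differ from germline followed the switched share (r = 0.991, permutation p = 0.000223, adjusted p = 0.00112; rho = 0.905, permutation p = 0.00456; 0.942 without knockouts 1 and 3; 0.988 within groups). Values within groups pool both groups after centring each on its mean, and no relation was tested in each group alone. Switched reads ran from 682 to 18993 in knockouts and from 14461 to 26179 in controls, so the knockouts can carry these values. Among controls, control 1 had the most switched reads but fewer VH reads (39035) than control 2 (53071) and control 4 (45241). VH reads also followed IGHM reads (r = 0.654, permutation p = 0.0354; rho = 0.738, permutation p = 0.0458; 0.679 without control 1 and knockout 4; 0.674 within groups), and IGKC reads did so too (r = 0.679, permutation p = 0.0248; rho = 0.738, permutation p = 0.0458; 0.691 without the same samples; 0.709 within groups), so the number of reads in a library remains open as a part of the relation. Sequencing errors in the V ends also remain open, since 23.2% of clonotypes with at least 3 reads differed from germline, against 27.3% of those with 1 read. How many of these differences come from germline genes or alleles absent from the reference was not tested. The share of such cells was not measured, unrearranged transcripts of switched constant regions in pro-B cells were not told apart, and a difference in it between the groups may be biological or come from the sort.

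Fewer heavy-chain CDR3 sequences in the knockouts could come from fewer reads, from a few expanded clones or from fewer cells. At equal reads the fold was 0.633 with all knockouts below all controls, which argues against fewer reads as the whole cause. At equal CDR3-spanning reads the fold was 0.677 with all clonotypes (120 reads), where controls gave 109 distinct sequences. It was 0.848 without the 10 largest of each sample (76 reads), where controls gave 72.2. Both control values are near the ceiling, so how far expanded clones account for the difference stays open. Fewer cells cannot be told apart from a smaller repertoire, since IGHM reads had a fold of 0.915 with a wide spread and cell numbers were not used here. An effect of the Setd2 knockout on the repertoire and fewer switched cells in the knockout samples both stay open.

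Knockout 3 shared 8 of its 73 heavy-chain CDR3 sequences with control 3, or 10.96% (95% Wilson interval 5.66 to 20.2), each with 1 read in knockout 3. Reads of control 3 assigned to knockout 3 may be the source, and the shared sequences held 3.50 reads in control 3 on average against 2.46 for all of its sequences (permutation p = 0.0840 over 100000 draws), which does not decide it. Junctions that arise repeatedly in different mice would be shared with the other controls too. Knockout 3 shared 0, 0, 8 and 1 sequences with controls 1 to 4, and 0 of the 8 were in any of the other 6 samples. Pairs of controls shared 0.301% to 0.749% of the smaller sample's sequences. These values argue against such junctions as the source of the 8 as a set. Their mean length was 13.1 amino acids against 11 for 18 sequences shared between controls (permutation p = 0.0761), which does not decide it. The largest clonotypes of knockout 3, with 9 reads, and of knockout 4, with 203 reads, each had 1 read in control 4, so single shared reads were not limited to this pair. No explanation tied to the knockout was tested.

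Other splits of the 8 samples into groups of 4 were run for each test across V genes. For heavy V usage, light V usage, heavy segment reads and light segment reads the real split gave 0 genes past the threshold, so each of the 35 splits necessarily gave as many, and the comparison says nothing about chance. The highest count in another split was 1, 0, 2 and 0 genes in that order.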
